A study of Mus musculus with 3 samples.

How the data were processed

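RNA attached to chromatin was measured in 3 libraries of mouse bone-marrow-derived macrophages, cells grown from C57BL/6J bone marrow. Per the labels, the cells had 100 ng/ml lipid A for 12 h, were washed out for 12 h and had 100 ng/ml lipid A again for 90 min. Lipid A is the part of bacterial lipopolysaccharide that Toll-like receptor 4 recognises. The chromatin fraction was isolated, ribosomal RNA was depleted and total RNA was sequenced. The labels number the libraries as biological replicates 1 to 3 of 1 condition. They list 1 µg of starting RNA for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3. They do not say whether the replicates came from separate cultures or animals, so the spread given here is that between these libraries and may be partly technical.

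Per the file headers and the text listed with each sample, the authors deposited a gene table and a transcript table made from alignments to the transcriptome, and a further transcript table made from the sequence reads directly. All used the mm10 assembly and the GENCODE M21 annotation. The aligner and the quantifiers are not given in the sources used here. The deposited expected counts are estimated counts that need not be whole. The deposited TPM, a length-corrected transcript abundance, are relative to all features of a library, spike-ins and transfer RNAs included. The deposited tables also give an effective length in bases for each feature, and the transcript tables from alignments give a percent of each gene's abundance on each transcript, per the file headers. That percent was not used here, and the share of a gene on each kind of transcript was computed from transcript TPM. Whether the counting used strand is not given in the sources used here, so a gene and an overlapping antisense gene cannot be separated with certainty.

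All 55536 gene identifiers of the M21 annotation were matched by identifier and version. The gene table held 26345 further rows that are no gene of the annotation. They took 1.34% of the expected counts in replicate 1, 0.292% in replicate 2 and 0.416% in replicate 3, and were left out of library sizes. Total expected counts were 12671700, 21747001 and 16915406 in replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.237, 0.138 and 0.177 CPM in the 3 libraries. These floors cover counting error only. Gene sums of the transcript table made from alignments differed from the gene table by at most 0.04 TPM, so that table was used for transcript shares.

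With 1 condition and no untreated cells, no comparison between conditions was possible. Comparisons were made between gene lists within each library. The level of a list was the median over its members of log2(TPM + 1), and the difference between 2 lists was taken within each library. It is given as mean and SD over 3 libraries with an exact two-sided sign-flip permutation test. With 3 libraries this exact test cannot go below p = 0.25, so nothing was called. A fold is on the log2(TPM + 1) scale and understates differences of low genes. Lists were also placed among 10000 random lists of the same size from protein-coding genes with a mean TPM of at least 0.1. Genes are not independent replicates, so these percentiles only describe the libraries. A gene counted as detected at a TPM of at least 1 in each library. The retained-intron share was the share of a gene's transcript TPM on transcripts annotated as retained intron. It was taken for genes with such a transcript and a TPM of at least 1 in each library. The inflammatory genes were the cytokine, chemokine, NF-kB, negative regulator, interferon-stimulated, immediate-early and antimicrobial lists. The comparison genes were the housekeeping, TLR4 signalling, glycolysis, chromatin and macrophage identity lists.

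Lists, comparisons, tests and most alternatives were fixed before the data were examined. The rule for named genes took the 10 protein-coding genes, mitochondrially encoded genes apart, and the 10 noncoding genes with the highest mean TPM. It also took the 3 highest members and the lowest member of each list, and the highest member of each other-lineage list. It always took Tnf, Il6, Il1b, Il12b, Il10, Il1rn, Nfkbia, Tnfaip3, Irak3, Socs3, Cxcl10, Ccl5, Lcn2, Saa3, Nos2, Ifnb1, Fos, Egr1, Malat1 and Neat1. Last, it took the 5 genes with the largest SD of log2(TPM + 1) among genes with a mean TPM of at least 10. A gene outside the rule is marked where it is named, and some genes that the rule takes are not reported here. One listed noncoding RNA, Norad, matched no gene symbol and has no value.

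Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave TMM factors, log2 CPM with a prior count of 1, and the biological coefficient of variation from an intercept-only design. DESeq2 1.42.0 gave alternative size factors. Both ran in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. A chi-square comparison of counts was made for each pair of libraries. On simulated counts with a coefficient of variation of 20% over 13532 genes, the estimate for the spread between the 3 libraries lay between 19.8% and 19.9%. For the difference between 2 list medians, planted log2 differences of 0, 1 and 2 over 200 genes were recovered as 0.0033, 1.01 and 1.99.

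After the data were seen, differences between pairs of libraries were compared with the GC content of transcripts, averaged per gene. This used 9688 protein-coding genes with a mean TPM of at least 1, of which 12 had no GC value. Trends were removed with lowess, fraction 0.3. In simulations over 9676 genes with a planted GC trend, list shifts of 0 and -1 were recovered as -0.030 and -1.07. Libraries were compared in pairs. A first comparison of replicate 2 with the mean of replicates 1 and 3 was set aside, because it grouped libraries by the outcome measured. The alternatives chosen in advance were another pseudocount, a minimum level for list members, means in place of medians, count-based scaling without length correction, the other transcript table, TPM rescaled to protein-coding genes, and each library left out in turn. The rescaled TPM was not applied to the comparisons of nuclear RNAs and of other-lineage markers. In the other comparisons it kept only protein-coding members, so a list could lose members in that setting. Counts of list members with at least 10 TPM without each library, and the removal of GC and length trends, were added after the data were seen.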

Results

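The data describe RNA on chromatin of mouse macrophages that met lipid A a second time. The 3 libraries form 1 group, and unstimulated cells or cells with a single stimulation were not analysed here. Total expected counts were 12671700 in replicate 1, 21747001 in replicate 2 and 16915406 in replicate 3. All positions are on mm10 and all levels are TPM from the gene table, as mean ± SD with n = 3 unless stated. Protein-coding genes, mitochondrially encoded genes apart, held 34.1%, 27.4% and 29.4% of TPM in replicates 1, 2 and 3. Their levels, spreads and counts at a TPM limit therefore also depend on how much other features held. With TPM rescaled to protein-coding genes, H2-K1 had 6171 ± 696 instead of 1853 ± 91.4 TPM, and Tnf 1514 ± 88.7 instead of 458 ± 55.6. A TPM of at least 1 in each library was reached by 11883 genes, of which 9039 were protein-coding and 251 were lincRNA genes. The count of detected genes was 7162 at 5 TPM and 19163 in the other transcript table.

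The protein-coding genes with the highest mean levels in the gene table were as follows. Lilrb4a and Lilr4b, neighbouring genes for receptors of myeloid cells on chromosome 10, led with 3416 ± 1554 and 2370 ± 1039 TPM. Tnfaip2 had 1906 ± 557 TPM, Malt1, which encodes a signalling protease upstream of NF-kB, 1859 ± 866, and the class I histocompatibility gene H2-K1 1853 ± 91.4. Ikbke, which encodes an IkB kinase-related enzyme and lies on chromosome 1 from 131254343 to 131279606, had 1681 ± 91.2 TPM. The transcription factor gene Zeb2 had 1392 ± 509 TPM, Acod1, which encodes the enzyme that makes itaconate, 1306 ± 386, Fyb 1226 ± 183 and the antiviral gene Mx1 1113 ± 459. The order differed between libraries and tables: in the other table Lilr4b, with 1847 TPM, lay below Ikbke with 2499 and Tnfaip2 with 2468, and in replicate 2 it lay below H2-K1 and Ikbke. H2-K1 had 1165 TPM in the other table, the lowest of these genes there. The Lilr genes are close relatives, and how reads were divided between them is uncertain.

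Noncoding RNAs took much of the signal, and their TPM had wide spreads. Part of that signal came from Gm26917 and Gm42418, beside or within an annotated ribosomal RNA gene on chromosome 17, as described below. Rmrp, the RNA of a mitochondrial RNA-processing ribonuclease, had 88697 ± 51831 TPM, and 31186 in the other transcript table. A second, overlapping Rmrp entry annotated as a lincRNA had 14975 ± 13680 TPM, 8176 without replicate 2 and 7058 in the other table, so the split between them is uncertain. Malat1, a nuclear RNA of nuclear speckles at 5795690 to 5802672 on chromosome 19, had 26721 ± 11190 TPM. Rn7sk, which regulates transcription elongation, had 16913 ± 4789 TPM, or 8211 in the other table, and Neat1, the scaffold of paraspeckles, 1695 ± 120. The snoRNAs Gm22988, Gm26447, Snord15b and Gm25776 had 75042 ± 26839, 49680 ± 16340, 28966 ± 6631 and 14279 ± 786 TPM. In the other transcript table they had 7142, 2283, 3010 and 1424 TPM. Genes of snRNA, snoRNA and scaRNA together held 39.5% ± 5.37 of TPM and 0.445% ± 0.091 of counts.

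The first comparison between lists concerned the cell fraction: nuclear-retained noncoding RNAs against ribosomal protein genes, whose mature mRNAs are mostly cytoplasmic. RNA of another cell fraction was not analysed here, so this difference in level does not show enrichment on chromatin. The 15 noncoding RNAs had a median of 37.8 ± 6.93 TPM and the 84 ribosomal protein genes a median of 19.8 ± 3.33 TPM. Rpl10, Rps9 and Rpl5 led the ribosomal protein genes with 103.4 ± 7.67, 98.0 ± 26.0 and 58.2 ± 8.05 TPM, and Rpl10l was at 0. The log2 difference was 0.90 ± 0.49 and positive in 3 of 3 libraries, with an exact sign-flip p = 0.25, the smallest that 3 libraries allow. Its size depended on the setting: it was 3.56 on TMM counts without length correction and 2.42 with low members left out. Mitochondrially encoded genes held 0.0637% ± 0.0273 of counts, with mt-Co1 at 307 ± 118, mt-Atp8 at 236 ± 134 (80.2 in the other table) and mt-Nd6 at 77.8 ± 24.4 TPM. The transfer RNA gene mt-Tp, whose effective length in the gene table is 0, was listed at 0 there and had a mean of 21.3 TPM in the other table. The 68 replication-dependent histone genes had a median of 0.378 ± 0.166 TPM. By mean they were led by Hist2h2aa2 at 12.6 ± 5.53, Hist2h2ac at 8.66 ± 2.16 and Hist3h2a at 6.93 ± 2.07 TPM. In replicate 1 Hist3h2a, with 9.32 TPM, lay above the other 2. In the other table Hist2h2ac, with 6.79 TPM, lay above Hist2h2aa2 with 6.20.

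Transcripts annotated as retaining an intron held a large part of the TPM of protein-coding genes. Shares were computed on annotated transcripts only, so they cannot tell intron retention from RNA that was not yet spliced. Retained-intron transcripts held 39.7% ± 2.13 of the TPM of these genes, or 35.1% in the other transcript table, and transcripts annotated as protein-coding 47.6% ± 2.34. Inflammatory genes had a median retained-intron share of 46.9% ± 2.44 over 58 genes, and the comparison genes 48.0% ± 2.43 over 57 genes. The difference of -1.17 ± 2.59 points was smaller than its spread between libraries, with an exact sign-flip p = 0.75. It was -3.23 ± 1.23 points for genes with at least 5 TPM, larger than its spread, but 0.088 points without replicate 3 and 1.32 points with means over genes. Over all 5882 protein-coding genes with such a transcript the median share was 48.1% ± 2.41. Inflammatory lists lay on both sides of it, with antimicrobial effectors at 62.3% ± 4.40, chemokines at 59.2% ± 4.17, interferon-stimulated genes at 45.2% ± 2.97, negative regulators at 42.3% ± 0.917 and NF-kB genes at 41.2% ± 6.00. Ribosomal protein genes had 59.5% ± 2.37 and macrophage identity genes 21.2% ± 1.66. Most of these medians rest on few genes. Antimicrobial effectors, chemokines and macrophage identity genes had 7 each, and negative regulators 8. NF-kB genes had 12, interferon-stimulated genes 20 and ribosomal protein genes 63. The SDs are between libraries and do not show the spread between genes: among macrophage identity genes, Fcer1g had 21.7% and Ctsb 66.5%. Some shares depended on the table: in the other transcript table macrophage identity genes had 30.4% and NF-kB genes 34.6%.

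Macrophage genes were present, and nearly all markers of other lineages were close to 0. Of the 20 macrophage identity genes, 19 had at least 1 TPM and 16 at least 10 TPM in each library, with a median of 31.1 ± 6.85 TPM. Adgre1, which encodes F4/80, had 422 ± 65.5 TPM, the protease gene Ctsb 220 ± 46.8 and the Fc receptor gene Fcer1g 163 ± 12.8, and Cebpa was lowest with 0.537 ± 0.336. In the other table Fcer1g had 294 TPM and lay above Ctsb with 280. Of 60 markers of neutrophils, T cells, B cells, fibroblasts, dendritic cells, erythroid and endothelial cells, 3 had at least 1 TPM in each library. The log2 difference between the lists was 4.96 ± 0.29, positive in 3 of 3 libraries, with an exact sign-flip p = 0.25. It was 8.08 with a pseudocount of 0.1 and 9.04 on TMM counts. It was 2.08 when members below a mean of 1 TPM were left out. Only erythroid and endothelial markers then remained for the other lineages, kept because their levels were high.

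The highest other-lineage markers differed widely in level. Vwf, an endothelial and platelet gene, had 25.5 ± 10.4 TPM, and the erythroid gene Alas2 had 4.43 ± 1.02, or 9.91 in the other table. The highest neutrophil, T cell, B cell, fibroblast and dendritic cell markers were S100a9 at 0.183 ± 0.161, Trac at 0.177 ± 0.127, Ighm at 0.050 ± 0.056, Pdgfrb at 0.277 ± 0.064 and Zbtb46 at 0.730 ± 0.161 TPM. Zbtb46 had 1.81 TPM in the other table.

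**Figure D1:**
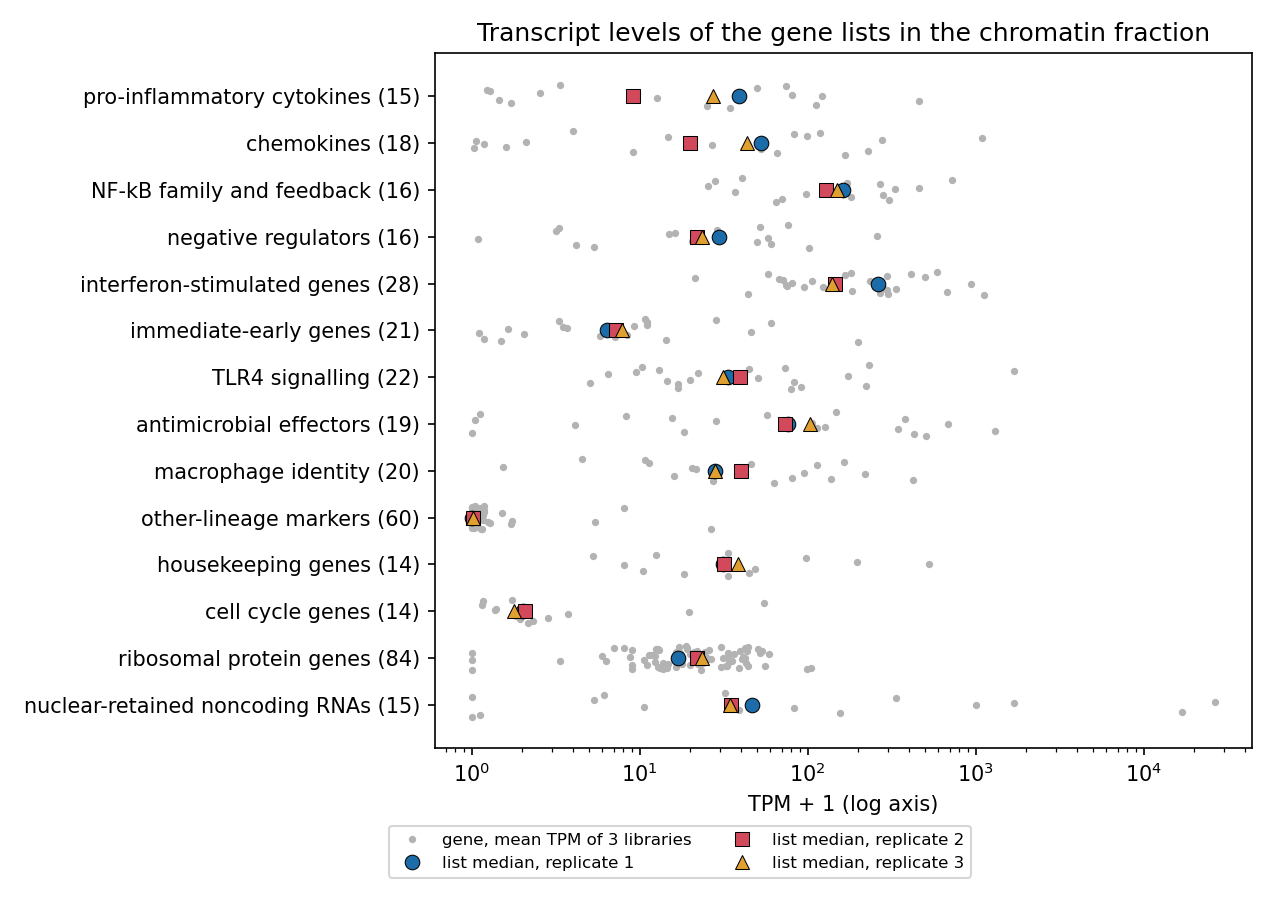
Levels of 14 gene lists on a logarithmic axis of TPM + 1, with the number of members in brackets. Grey points are genes (mean of 3 libraries) and coloured symbols are the list median in each library; interferon-stimulated genes have medians of 263, 144 and 138 TPM in replicates 1, 2 and 3, and the cytokine median of replicate 2 is 8.15 TPM.

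Other inflammatory lists were compared in level with the pro-inflammatory cytokines. Without cells before the second stimulation, these levels do not show what it induced. Tnf, the tumour necrosis factor gene on chromosome 17 from 35199381 to 35202007, was the highest cytokine gene with 458 ± 55.6 TPM. Il1b had 120 ± 47.4 and Csf1, the macrophage growth factor gene, 111 ± 44.2 TPM. Il12b had 24.1 ± 14.9 TPM, Il6 11.7 ± 9.94 and Csf3 0.237 ± 0.0757. Without replicate 1, Il6 was at 6.09 TPM. The 15 cytokine genes had a median of 24.1 ± 14.9 TPM, and 7 of them had at least 10 TPM in each library. In each library this median was the level of Il12b, so each main difference from cytokines below is a difference from that gene. With means over members, antimicrobial effectors lay 1.68 ± 0.31 and chemokines 0.56 ± 0.13 log2 units above cytokines. NF-kB genes then lay 3.10 ± 0.23 and negative regulators 0.39 ± 0.23 above them. The median was 37.8 TPM in replicate 1, 8.15 in replicate 2 and 26.4 in replicate 3, so the spread between libraries was large beside the mean.

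Chemokine genes, which encode attractants for leukocytes, had a median of 37.8 ± 17.02 TPM over 18 members, of which 9 had at least 10 TPM in each library. Ccl5 had 1097 ± 212 TPM, Cxcl10 276 ± 114 and Ccl4 227 ± 61.4, and Cxcl5 was lowest with 0.033 ± 0.035, or 1.76 in the other table. Cxcl10 and Ccl4 changed order in the other table, with 177 and 380 TPM, and in replicate 3. Chemokines lay 0.64 ± 0.30 log2 units above cytokines, positive in 3 of 3 libraries, with an exact sign-flip p = 0.25. The difference was 1.17 with TPM rescaled to protein-coding genes, a setting that also dropped list members of other gene types. A pseudocount of 0.1, which acts much as rescaling does within a library, gave 0.67. The chemokine median was 52.0, 19.0 and 42.5 TPM in replicates 1, 2 and 3.

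All 16 genes of NF-kB and its feedback had at least 10 TPM in each library, and 9 had at least 100. Tnip3, an inhibitor of NF-kB signalling, had 726 ± 235 TPM, Nfkb1, a subunit, 460 ± 126, Traf1 332 ± 94.5 and Nfkbib, the lowest, 24.5 ± 3.81. The inhibitor genes Tnfaip3, which encodes A20, and Nfkbia, which encodes IkBa, had 305 ± 111 and 278 ± 38.1 TPM. The median of 146 ± 16.7 TPM lay 2.77 ± 0.93 log2 units above cytokines in 3 of 3 libraries, with an exact sign-flip p = 0.25. The difference was 1.61 without members below a mean of 1 TPM and 3.83 on TMM counts.

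Negative regulators of Toll-like receptor and cytokine signalling were not separated from the cytokines by list medians. Rgs1 had 258 ± 152 TPM and the phosphatase gene Ptpn6 101.1 ± 12.8, but the order reversed in the other table, with 179 and 303 TPM. Next was Socs3, a feedback inhibitor of cytokine signalling, with 75.0 ± 17.8. Irak3, which encodes the inhibitory kinase IRAK-M, had 59.8 ± 1.84 TPM. Il1rn, the interleukin 1 receptor antagonist gene, had 14.04 ± 12.04 TPM, 7.31 without replicate 1 and 25.8 in the other table. Il10 had 3.18 ± 1.47 and Sigirr 0.0867 ± 0.150 TPM. The median of 24.1 ± 4.06 TPM lay 0.20 ± 0.91 log2 units from that of cytokines, above it in 1 of 3 libraries, with an exact sign-flip p = 1. The sign turned to -0.32 without replicate 2 and to -0.77 without members below a mean of 1 TPM, and the value was 1.31 on TMM counts. With means over members in place of medians the difference was 0.39 ± 0.23.

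Antimicrobial effectors had a median of 83.2 ± 16.3 TPM over 19 members, of which 13 had at least 10 TPM in each library. Acod1 led with 1306 ± 386 TPM. Clec4e, which encodes the receptor Mincle, had 681 ± 199 TPM, the superoxide dismutase gene Sod2 508 ± 155 and the acute-phase gene Saa3 379 ± 83.4. Nos2, the inducible nitric oxide synthase gene, had 17.3 ± 9.01 TPM, or 44.2 in the other transcript table, and Lcn2, which encodes an iron-binding trap, 3.09 ± 0.20. Slpi had 0 counts in every library, which allows up to 0.614, 0.387 and 0.491 TPM in replicates 1, 2 and 3, though its mean was 0.409 TPM in the other transcript table. The list lay 1.96 ± 1.01 log2 units above cytokines in 3 of 3 libraries, with an exact sign-flip p = 0.25. By library the differences were 0.98, 3.00 and 1.91.

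**Figure D2:**
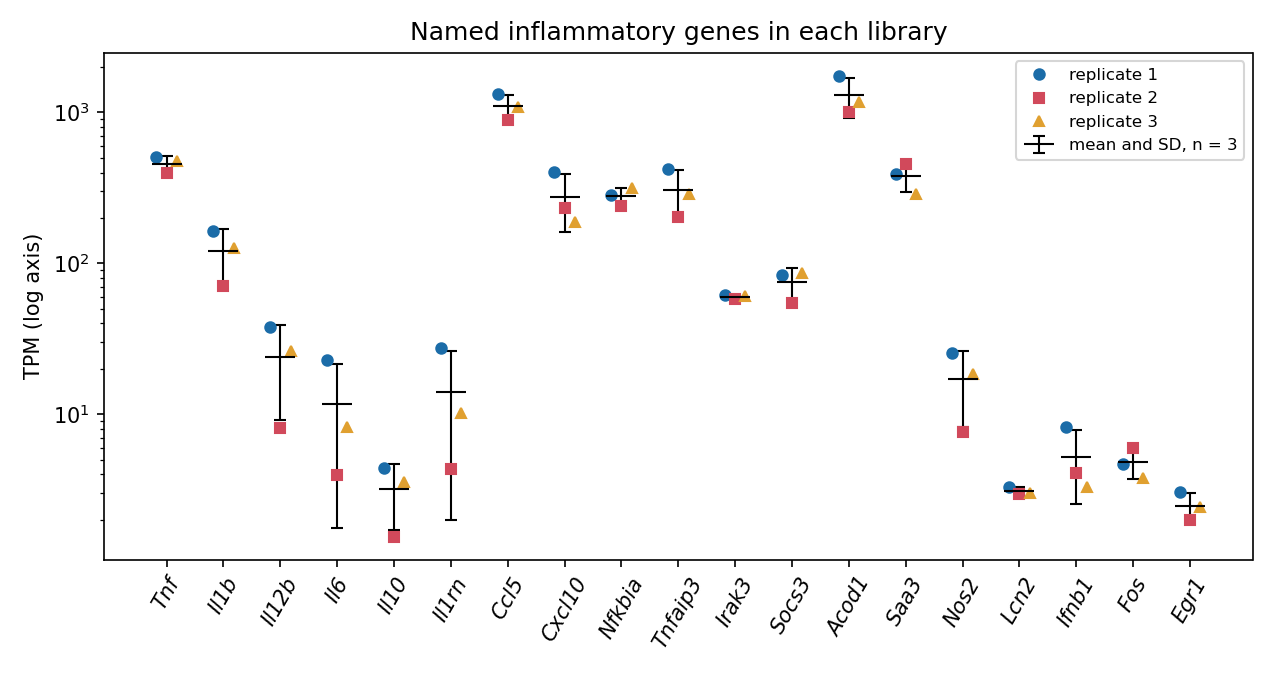
TPM of 19 inflammatory genes on a logarithmic axis. Symbols are the 3 libraries, and bars the mean and SD with n = 3; Irak3 lies between 57.7 and 61.3 TPM, and Il6 between 3.99 and 22.9 TPM.

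Interferon-stimulated genes had the highest mean list median among the inflammatory lists, although in replicate 3 the NF-kB genes were higher, with 149 against 138 TPM. All 28 had at least 10 TPM in each library and 17 had at least 100, with a median of 182 ± 70.3 TPM. Mx1 had 1113 ± 459 TPM, Oasl2 933 ± 306, Rsad2, which encodes viperin, 678 ± 531 and Isg20, the lowest, 20.4 ± 10.1. Rsad2 had 1291 TPM in replicate 1, and a mean of 372 TPM without it. Immediate-early genes, which answer a stimulus within minutes, had a median of 6.15 ± 0.756 TPM, and 5 of 21 had at least 10 TPM in each library. Klf6 had 198 ± 67.2 TPM, Junb 59.5 ± 11.4 and Atf3 45.0 ± 17.2, while Fos had 4.83 ± 1.12, Egr1 2.48 ± 0.533 and Fosl1 0.107 ± 0.185. Junb and Atf3 changed order in the other table, with 44.8 and 80.7 TPM, and in replicate 1.

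Interferon-stimulated genes lay 4.61 ± 0.66 log2 units above immediate-early genes in 3 of 3 libraries, with an exact sign-flip p = 0.25. By library the differences were 5.37, 4.33 and 4.14. Of 7 interferon genes, 6 had a TPM of 0 in every library. Ifnb1 had 5.22 ± 2.67 TPM. Ifng had 0 counts, which allows up to 0.469, 0.284 and 0.363 TPM in replicates 1, 2 and 3. Ifna1 also had 0 counts, which allows up to 0.757, 0.493 and 0.621 TPM, and so did Ifnl2, which allows up to 0.556, 0.347 and 0.441 TPM.

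Genes of the receptor pathway were all detected. All 22 genes of TLR4 signalling had at least 1 TPM in each library, with a median of 33.7 ± 4.15 TPM. Ikbke led, followed by the kinase genes Irak2 at 232 ± 32.3 and Tbk1 at 220 ± 46.7 TPM, and Tab1 was lowest at 4.03 ± 1.47. In the other table Irak2 had 395 and Tbk1 285 TPM. The 14 housekeeping genes had a median of 32.9 ± 3.98 TPM, with Actb at 527 ± 47.3, Eef1a1 at 195 ± 18.8, B2m at 97.3 ± 24.98 and Pgk1 at 4.25 ± 0.791. The 16 genes of histone modifiers and chromatin had a median of 52.4 ± 1.36 TPM, led by Brd2 at 277 ± 70.7, Chd4 at 166 ± 27.2 and Ncor1 at 116 ± 7.69. Kdm5b was the lowest at 2.80 ± 0.746 TPM.

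The lists were also placed among random lists of 12401 protein-coding genes, whose median was 5.67 ± 0.329 TPM. Interferon-stimulated genes, NF-kB genes and antimicrobial effectors lay at percentile 100 ± 0, chemokines at 99.4 ± 1.02 and cytokines at 90.7 ± 15.9. High percentiles were not particular to inflammatory lists: ribosomal protein genes and chromatin genes also lay at 100 ± 0, and housekeeping genes at 99.9 ± 0.125. Against genes with a mean of at least 1 TPM, chemokines lay at 96.8 ± 5.48 and cytokines at 78.0 ± 36.1, with cytokines of replicate 2 at 36.4. Immediate-early genes lay at percentile 55.4 ± 4.03, and at 12.3 ± 2.78 against that background.

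The libraries differed from one another in ways that touch these levels. Spearman correlations across 13344 genes, which are not independent replicates, were 0.896 for replicates 1 and 2, 0.909 for 1 and 3, and 0.941 for 2 and 3. Chi-square values per degree of freedom of 175, 99.0 and 33.6 showed no pair to be 1 library deposited again. The biological coefficient of variation was 26.6% over 13163 genes, and 17.8% without replicate 1. The largest spreads by the naming rule were all of small RNAs: Snord22, Gm24924, Gm26244, Gm24233 and Gm22786. Snord22 had 17361 TPM in replicate 1 and was listed at 0 in replicates 2 and 3. Its expected counts were 285, 939 and 750 in replicates 1, 2 and 3. Its effective length was 0 in replicates 2 and 3, so the TPM of 0 listed there does not reflect its counts. The same held for Gm24233 and Gm22786.

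Differences that involved replicate 1 followed the GC content of transcripts, a relation examined after the data were seen. Across genes, which are not independent replicates, the Spearman correlation with GC content was -0.40 for replicate 1 minus 2, -0.41 for 1 minus 3 and 0.096 for 2 minus 3. Genes were split into 5 equal bins by GC content. In the lowest and the highest bin, the median log2 difference was 0.16 and -0.58 for replicate 1 minus 2. For replicate 1 minus 3 it was 0.11 and -0.50, and for replicate 2 minus 3 it was -0.025 and 0.079.

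**Figure D3:**
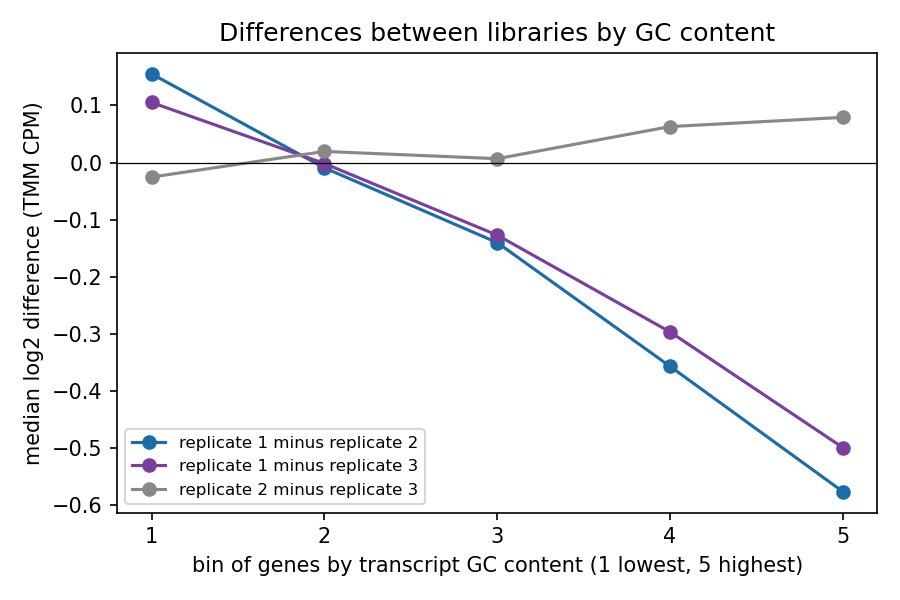
Median log2 difference between libraries (TMM log2 CPM, vertical axis) in 5 bins of protein-coding genes by GC content (horizontal axis, lowest to highest). Each line is a pair of libraries; both pairs with replicate 1 fall, to -0.58 and -0.50, and the pair of replicates 2 and 3 stays between -0.025 and 0.079.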

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

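These signals lie outside the genes that were compared, and lie above the 3 counts that a count of 0 allows; no explanation was tested. Reads assigned to phiX174, a phage genome commonly added to sequencing runs as a control, were 1.34% of expected counts in replicate 1, 0.292% in replicate 2 and 0.416% in replicate 3. The 96 ERCC spike-ins had 0 counts in every library. Rows named only by a number had 17, 21 and 20 counts in replicates 1, 2 and 3, spread over 5 of 26248 such rows.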

How the results depend on the processing

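Signs of the list differences held in every alternative chosen in advance except for negative regulators minus cytokines and the retained-intron difference. Some alternatives could not turn a sign. Leaving out a library cannot do so for a comparison positive in 3 of 3 libraries. TMM and DESeq2 scaling nearly cancels within a library, so both mainly show the effect of omitting length correction and are not separate checks. With 3 libraries the exact sign-flip test cannot go below p = 0.25, so it can call no difference, and causes of the shifts were not tested. Without members below a mean of 1 TPM, negative regulators minus cytokines turned to -0.77, NF-kB genes minus cytokines was 1.61, macrophage minus other-lineage genes 2.08, and nuclear RNAs minus ribosomal protein genes 2.42. On TMM counts these were 1.31, 3.83, 9.04 and 3.56, and with DESeq2 size factors 1.31, 3.83, 9.02 and 3.56. With members below a mean of 1 TPM left out, only erythroid and endothelial markers stood for the other lineages. Chemokines minus cytokines was 1.17 on protein-coding TPM, and macrophage minus other-lineage genes 8.08 with a pseudocount of 0.1. The protein-coding setting also dropped list members of other gene types, so the value of 1.17 need not come from rescaling. Nuclear RNAs minus ribosomal protein genes was 1.77 with means and 1.40 in the other transcript table. Protein-coding TPM was not applied to the comparisons of nuclear RNAs and of other-lineage markers.

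Leaving out each library gave 1.45 to 2.46 for antimicrobial effectors, 0.50 to 0.79 for chemokines, -0.32 to 0.50 for negative regulators and 2.25 to 3.13 for NF-kB genes, each minus cytokines. It gave 4.24 to 4.85 for interferon-stimulated minus immediate-early genes, 4.79 to 5.05 for macrophage minus other-lineage genes and 0.62 to 1.07 for nuclear RNAs minus ribosomal protein genes. The retained-intron difference was -2.04 to 0.088 points, 1.32 with means over genes and -3.23 for genes with at least 5 TPM. Leaving out each library gave the coefficient of variation 17.8% to 32.3%, the median correlation across genes 0.893 to 0.939 and the number of detected genes 12190 to 12412. That number was 7162 at 5 TPM and 19163 in the other table. Of 127 named gene levels, 65 moved by more than 1 SD in the other table. Member counts at 10 TPM without each library, added after the data were seen, stayed within 1 of those given.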

Other observations

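Lipid metabolism genes and markers of alternative activation were also measured. Targets of the LXR receptors and cholesterol efflux genes had a median of 32.9 ± 3.79 TPM over 8 genes, with the transporter genes Abca1 at 201 ± 12.8 and Abcg1 at 64.2 ± 7.08, the receptor gene Nr1h3 at 91.4 ± 21.1 and Scd2 at 3.77 ± 1.53. Genes of sterol synthesis and uptake had a median of 6.59 ± 1.55 TPM over 13 genes, with Hmgcs1 at 34.5 ± 9.44. The 16 glycolysis genes had a median of 17.7 ± 2.86 TPM, led by Pfkp at 107 ± 53.7, Pkm at 52.1 ± 13.7 and Pfkfb3 at 38.6 ± 12.7, with Slc2a1 lowest at 2.54 ± 0.876. The 10 M2-associated genes had a median of 0.463 ± 0.0603 TPM, with Il4ra at 43.8 ± 9.45, Tgm2 at 41.7 ± 5.22 and Mrc1 at 26.1 ± 5.06, and Retnla had 0 counts in every library. The 14 cell cycle genes had a median of 0.955 ± 0.142 TPM, although Mki67 had 54.0 ± 17.5, Pcna 18.5 ± 5.55, Top2a 2.74 ± 0.592 and Plk1 0.143 ± 0.10.

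Xist, the RNA that coats the inactive X chromosome, had 998 ± 60.9 TPM, and its antisense partner Tsix 0.090 ± 0.061. Among Y-linked genes, Kdm5d had 0.0067 ± 0.0058 TPM in the gene table and a mean of 6.64 TPM in the other table, and Eif2s3y had 0 counts in the gene table and a mean of 0.912 TPM in the other, so the tables differ on Y-linked signal. Besides Vwf, the endothelial gene Kdr, named after its values were seen, had 7.06 ± 5.57 TPM. Cdh5, also an endothelial gene and named likewise, had 0.0533 ± 0.0289 TPM. On chromosome 17, Gm26917 (39843013 to 39846341), Gm42418 (39846958 to 39848788) and the annotated ribosomal RNA gene CT010467.1 (39846353 to 39848827) lie side by side and partly overlap. Together they held 9.95%, 27.5% and 22.1% of expected counts in replicates 1, 2 and 3. Gm42418 lies within the span of the ribosomal RNA gene. Whether these counts are ribosomal RNA left after depletion was not tested. They were kept in the library sizes, although their share differed widely between libraries. CT010467.1 was named after its values were seen.

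The 3 patterns that follow were chosen after the data were seen, and so were their tests, except the test of the depth of replicate 1, whose prediction was written before its result. No biological explanation was tested, since the design has 1 group. Cytokine genes were lower in replicate 2: on TMM counts, relative to all genes, 10 of 11 cytokine genes were lower than in replicate 1 (median log2 difference -1.15) and 10 of 11 lower than in replicate 3 (median -0.79). In the same 2 pairs, chemokines were lower in 13 and 11 of 13 genes, NF-kB genes in 14 of 16 both times and immediate-early genes in 10 and 14 of 17, whereas interferon-stimulated genes were lower in 25 and 12 of 27, antimicrobial effectors in 13 and 8 of 16, negative regulators in 12 and 8 of 15 and macrophage identity genes in 10 and 5 of 19. For replicate 1 minus 3 the cytokine median was 0.44, with 2 of 11 genes lower in replicate 1. In that pair it was 0.86 for interferon-stimulated genes and 0.59 for antimicrobial effectors, with 1 of 27 and 2 of 16 lower in replicate 1. For replicate 2 minus 3 these 2 lists had medians of 0.11 and -0.024, so there replicate 1 stood apart. GC content is argued against as the whole cause of the cytokine pattern. The cytokine median against replicate 1 was -1.02 after a GC trend was removed, with 10 of 11 genes still lower. A lower share of nascent RNA in replicate 2 stays open: the immediate-early median was -0.28 against replicate 1 and -0.66 after a GC trend was removed, but -0.17 against replicate 3; the bounds of this test were revised after a first value was seen, to take in the values with the GC trend removed, and under the first bounds the same test had counted against this explanation. Cytokine levels fell from replicate 1 to 3 to 2, which is also the order of the amounts of starting RNA. The amount of starting RNA cannot be told apart from the replicate, because the 3 libraries had 3 different amounts.

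Replicate 1 stood apart: the SD of log2 ratios over 9688 genes was 0.69 for replicates 1 and 2, 0.60 for 1 and 3, and 0.43 for 2 and 3. Lower depth of replicate 1 is argued against as the whole cause. Among 1657 genes with at least 1000 counts in each library these SDs were 0.50, 0.40 and 0.31. The gaps between pairs were narrower there, so depth as part of the cause is not excluded. GC content is argued against as the whole cause, because the smaller SD with replicate 1 was 0.55 after GC trends were removed, beside 0.43 for replicates 2 and 3. GC content may be part of the cause: a GC trend removed 15.1% of the variance for replicates 1 and 2 and 15.5% for 1 and 3, but 0.815% for 2 and 3. What in the preparation of replicate 1 differed was not tested.

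Small RNAs had very high and erratic TPM. Of 65 snRNA, snoRNA and scaRNA genes with at least 20 counts in each library, 34 had a mean effective length under 10 bases. Over these 34 the gene table exceeded the other transcript table by a median log2 ratio of 2.44, while protein-coding genes had a median of -0.33. This is consistent with effective lengths of a few bases in the gene table inflating TPM, a hypothesis, since both tables were made from the same reads and neither is a reference. Gm22988, with an effective length of 3.67 bases, had 75042 TPM in the gene table and 7142 TPM in the other. Any such inflation would lower the TPM of all other genes, which are relative to the same total.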
